A study of Homo sapiens with 4 samples.

How the data were processed

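RNA sequencing libraries were made from total RNA of Hep-G2 cells that carried either a scramble shRNA or an shRNA against FTO, with 2 deposited tables per group and 4 in all. Per the labels' protocols, RNA was isolated with Trizol, treated with DNase and purified on RNeasy columns, and libraries followed Illumina's usual protocols. The selection of polyadenylated RNA, the read length and the strand setting were not given in the sources used here. Without a strand setting, reads of overlapping and antisense genes cannot be told apart, and reads shared by near-identical genes can be split or lost.

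The deposited values are raw read counts per Ensembl gene, with no normalization. Per the submitters' processing notes, TopHat2 2.1.1, HTSeq 0.6.0 and the human build hg19 were used, and the annotation release was not given in the sources used here. The tables list 62893 genes and no line of unassigned reads. Totals ran from 20047409 to 20706611 reads per table, and these totals count reads assigned to genes. Groups and replicate numbers come from the sample titles, in which the control is abbreviated, while the series' design text names it as the scramble.

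Gene symbols and gene types were matched by Ensembl identifier to GENCODE v29 tables, which gave a symbol for 51226 of the 62893 identifiers. Genes without a symbol held 0.7% of reads. That annotation is of another build (GRCh38) than the authors' and was used only for names, types, chromosome, gene order, transcript length and GC content, so no coordinates are given. Of 760 list members 750 were matched (98.7%), older symbols through RefSeq synonyms.

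Before averaging, the runs of each group were compared by a chi-square test of their counts over genes with at least 20 reads. As they did not differ detectably beyond sampling noise, the 2 runs of a group were pooled for every level and fold and counted as 1 sample. Folds are ratios of pooled CPM values, with library sizes scaled by the trimmed mean of M values (TMM), and carry exact 95% Clopper-Pearson intervals of the split of reads between the groups. A gene with no read in 1 group has a bound against 3 reads over the pooled runs, which leaves out the error of the other group's count. List medians were the same with such genes set to their bound. The intervals cover counting error only, and no culture-to-culture error can be had from these tables.

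The test fixed before the data were examined was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the 4 tables, with TMM, filterByExpr, no covariate, two-sided, and a Benjamini-Hochberg adjusted p under 0.05. It left 13767 genes and 2 residual degrees of freedom, and its common dispersion was 9.8e-05. As the runs show no detectable variation beyond sampling, its calls compare these libraries and not the conditions, and no p-value of a single gene is given. The 34 gene lists were also fixed before the data were examined: the m6A machinery, neighbours of FTO, liver functions, metabolism, cell cycle, stress, signalling, and markers of other cell types. For the 31 lists with at least 5 tested members, camera (limma 3.58.1, preset correlation 0.01) was run, and the list's median log2 ratio was ranked among those of 10000 random lists of the same size, matched on mean expression in 20 bins.

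Named genes followed a rule fixed before the data were examined: FTO; the 12 largest changes each way among called protein-coding genes with a symbol, a mean of at least 5 CPM and no overlap between the groups' runs; and in each list up to 4 called members each way with the smallest p. Genes named outside the rule are marked in the text, and some genes that the rule takes are not reported here. Transcript length and GC content were available for 13457 tested genes. Trends on length, GC and expression were fitted with mgcv 1.9.3 to those with a mean of at least 1 CPM, without the most strongly changed genes, and explained 3.5% of the deviance. Neighbouring genes were scanned in windows of 41 genes with at least 8 CPM and compared with 1000 shuffles of the gene order.

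Alternatives were other scalings, other low count filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each run, camera with an estimated correlation and fry. Added after the data were seen were scaling by plain library size, summed runs with an assumed coefficient of variation, the random-list criterion and removal of length, GC and expression trends. The test was checked on simulated data without variation beyond sampling. Over 13545 simulated genes edgeR made 8 false calls. It found 60.9% of 46 planted 1.25-fold, 86% of 50 2-fold, 97.9% of 48 4-fold and 100% of 47 8-fold changes. With a simulated dispersion of 0.01, over 13530 genes, it found 6.5%, 83.7%, 100% and 100% of 46, 49, 49 and 47 such changes, with 7 false calls. Few simulated genes changed, whereas 66.6% of tested genes passed in the data. The simulation therefore did not check the scaling or the number of calls.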

Results

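Gene expression was measured by RNA sequencing of total RNA from Hep-G2 cells, a human hepatoma-derived line that keeps many hepatocyte transcripts. The series set out to compare cells in which FTO, an enzyme that removes methyl groups from N6-methyladenosine in RNA, was knocked down with an shRNA against cells carrying a scramble shRNA. Each group has 2 deposited count tables, called run 1 and run 2 here, all from cells at passage 21. The tables held 20047409 and 20474554 gene-assigned reads for scramble and 20220271 and 20706611 for shFTO. The 2 runs of a group did not differ detectably beyond sampling noise and were counted as 1 sample. Over 13359 genes the chi-square of the scramble runs was 1.019 per degree of freedom (chi-square test, p = 0.0648), and over 13674 genes that of the shFTO runs was 1.013 (p = 0.142), whereas runs of different groups gave 118 to 120. The comparison is therefore of 1 sample with 1 sample and has no replicate check. The titles number the 2 tables of a group as replicates 1 and 2, but nothing in the labels says that they came from separate cultures.

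FTO (ENSG00000140718) was lower in both shFTO runs. The scramble runs held 594 and 550 FTO reads, or 31.4 and 28.5 CPM, the read count scaled for library size, and the shFTO runs held 116 and 128 reads, or 5.4 and 5.8 CPM. With the runs of each group pooled, the FTO transcript was 5.32-fold lower in the knockdown (95% counting interval 4.63 to 6.13), a log2 ratio of -2.41. Intervals here and after are exact Clopper-Pearson intervals on pooled reads and cover counting error only.

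**Figure D1:**
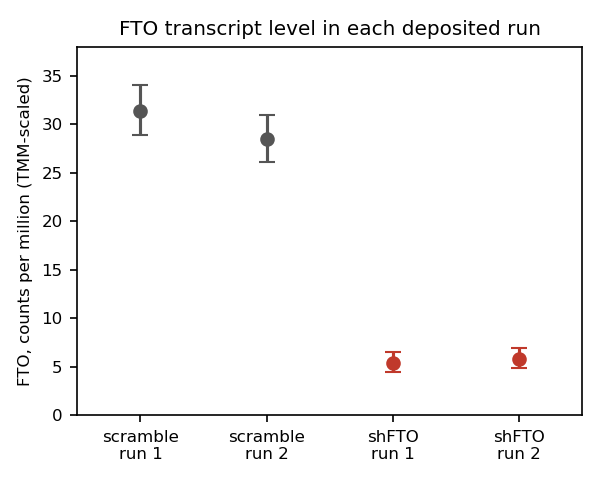
FTO transcript level in CPM (vertical axis, scaled with the trimmed mean of M values) in each of the 4 deposited runs, with scramble in grey and shFTO in red and bars showing exact 95% Poisson intervals of the reads. The scramble runs sit at 31.4 and 28.5 CPM and the shFTO runs at 5.4 and 5.8 CPM.

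The 12 largest decreases included the 3 fibrinogen genes and alpha-fetoprotein. The fibrinogen chains FGA (ENSG00000171560), FGB and FGG, which form the clot-forming plasma protein, were 78.9-fold (70.7 to 88.2), 52.9-fold (42.9 to 66.0) and 44.9-fold (41.6 to 48.5) lower. Alpha-fetoprotein, AFP (ENSG00000081051), the main fetal plasma protein and a hepatoma marker, went from 2053 to 28.8 CPM and was 71.3-fold lower (67.4 to 75.4). FABP1, the liver fatty acid binding protein, was 33.2-fold lower (32.1 to 34.4), and IGFBP1, a secreted binding protein of insulin-like growth factors, was 27.6-fold lower (26.7 to 28.6). The other 6 of the 12 largest decreases were PTPRN2, BPIFB2, TNNI2, ADAMTS2, HEY1, a Notch target, and HAL, the enzyme that starts histidine breakdown, between 20.5-fold and 60.4-fold lower.

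The transcripts furthest above scramble came mostly from genes with few reads there. C14orf132 (ENSG00000227051) had 3 and 2 reads in the scramble runs and 494 and 479 in the shFTO runs, a ratio of 171.5 with a wide counting interval of 73.3 to 529.5. UNC5B, a netrin receptor, was 146.8-fold higher (77.1 to 321.7) and MDFI 59.2-fold higher (28.5 to 148). The small GTPase RAB31 was 32.1-fold higher (23.2 to 45.8), and NPNT, an extracellular matrix protein, was 31.4-fold higher (24.5 to 41). GPR161, SYNPO, ATOH8, RBPMS2, PLCG2, GSTA2 and the adhesion receptor ADGRG1 completed the 12 largest increases, at 11.2-fold to 22.2-fold. GSTA2 shares long stretches of sequence with GSTA1 (3.89-fold higher), so reads may have been split between the pair. A further 7 genes had no read in scramble and at least 20 in shFTO, among them the biliary keratin KRT7 with 79 reads, at least 23.2-fold higher against a floor of 3 reads over the pooled runs, and CA4 with 103 reads, at least 30.3-fold higher. In the other direction ROBO3, MEP1A, PLG, RNASE7 and BHLHA15 had no read in shFTO, and plasminogen, PLG, with 31 scramble reads, was at least 11.7-fold lower. These genes were picked here for their zeros after the values were seen, although KRT7 and PLG were also members of fixed lists.

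**Figure D2:**
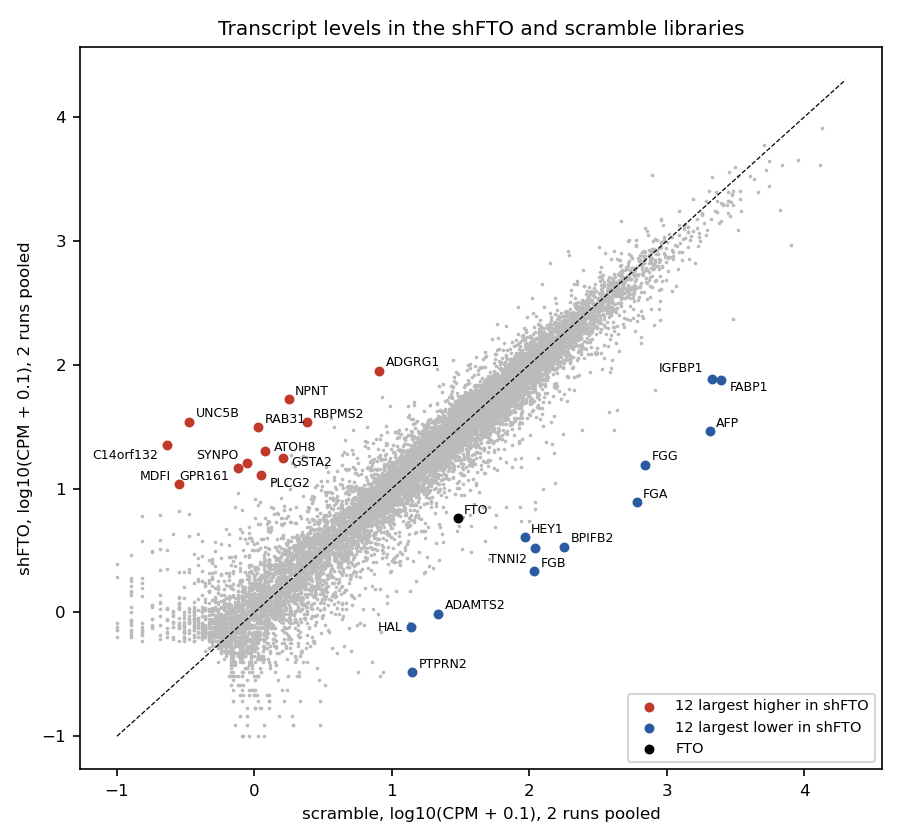
Pooled transcript levels of the tested genes in scramble (horizontal axis) and shFTO (vertical axis), both as log10 of CPM plus 0.1, with the dashed line marking equal levels. FTO is black, the 12 largest increases are red and the 12 largest decreases blue, and FGA, FGB, FGG and AFP lie far below the line.

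Of 13767 genes with enough reads, 704 were at least 2-fold higher and 847 at least 2-fold lower in the knockdown, with 216 and 214 of them changed at least 4-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4576 genes were higher, 4594 lower and 4597 did not pass. The spread in that test comes from runs with no detectable difference beyond sampling, so it compares these libraries and not the conditions. Most calls are of changes under 2-fold, with 1551 calls at least 2-fold. Over all tested genes, passing or not, the 5th and 95th percentiles of the log2 ratio were -1.13 and 1.02. If cultures were assumed to vary with a coefficient of variation of 0.2, a value chosen after the data were seen and not measured here, 391 genes would pass as higher and 500 as lower, and at 0.4 the numbers would be 55 and 61. The gene counts below are calls of the same test, and unless stated the count adjusted over the list alone was identical.

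Transcripts of proteins that hepatocytes secrete into plasma were lower as a group. Of 29 tested members, 27 were lower and 2 higher, 18 were at least 2-fold lower, and the median log2 ratio of -1.29 lay below those of all 10000 random lists matched on expression, whose central 95% ran from -0.25 to 0.12. Its camera call was lost when the correlation was estimated (adjusted p = 0.209 with an estimated correlation). That setting had 2 residual degrees of freedom, so here and below the loss of a call with it says little. Albumin, ALB, went from 13000 to 4059 CPM and was 3.2-fold lower (3.18 to 3.22). The fetuin gene AHSG was 3.71-fold lower (3.68 to 3.74), transferrin, TF, 2.03-fold (2.02 to 2.04) and SERPINA1, which encodes alpha-1-antitrypsin, 1.84-fold (1.83 to 1.86). The exceptions were coagulation factor V, F5, 1.36-fold higher (1.32 to 1.41), and KNG1, the kininogen gene, 2.42-fold higher (2.04 to 2.89). Of 12 acute phase genes 8 were lower and 3 higher (median -0.94, below all 10000 random lists). Camera did not call the acute phase list (adjusted p = 0.0667, or 0.476 with an estimated correlation). SERPINA3 was 3.83-fold lower (3.75 to 3.92), the haptoglobin gene HP 3.32-fold lower (3.14 to 3.52), and CEBPD, a transcription factor of the acute phase, 4.17-fold lower (3.81 to 4.57), whereas HAMP, which encodes the iron hormone hepcidin, was 2.36-fold higher (2.20 to 2.53).

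Hepatocyte transcription factors went both ways. Of 18 tested, 10 were lower and 7 higher (median -0.27, percentile 0.96 of random lists), and camera did not call the list (adjusted p = 0.41, or 0.513 with an estimated correlation). HNF4A was 1.32-fold lower (1.28 to 1.36), CEBPB 1.99-fold lower (1.89 to 2.1) and NR0B2, the small heterodimer partner, 3.06-fold lower (2.76 to 3.39), while FOXA1 was 1.43-fold higher (1.36 to 1.49) and CEBPA 3.16-fold higher (2.62 to 3.84). Of 13 oncofetal and progenitor genes 8 were lower and 4 higher (median -0.46, percentile 1.17), again without a camera call (adjusted p = 0.186, or 0.411 with an estimated correlation). Beside AFP, the fetal growth factor gene IGF2 was 8.57-fold lower (8.48 to 8.66), with reads that may include a readthrough transcript from INS, and DLK1 was 2.71-fold lower (2.65 to 2.78). Ductal keratin KRT19 was 1.97-fold higher (1.92 to 2.02) and EPCAM 1.29-fold higher (1.26 to 1.32). After removal of transcript length, GC and expression trends the oncofetal median was -0.25 and lay inside the range of random lists.

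Hypoxia response and glycolysis transcripts were mostly lower, with camera giving each list an adjusted p = 0.209 with an estimated correlation. All 20 tested hypoxia genes were lower, 13 of them at least 2-fold (median -1.33), and 20 of 22 glycolysis genes were lower, 11 at least 2-fold, with none higher (median -0.94). Both medians lay below all 10000 random lists, and with the 3 shared genes left out they were -1.03 over 17 genes and -0.78 over 19, again below all. BNIP3, a mitophagy receptor, was 4.14-fold lower (4.0 to 4.29), the collagen cross-linking enzyme LOX 3.63-fold (3.46 to 3.81), hexokinase HK2 3.49-fold (3.39 to 3.60) and the glucose transporter SLC2A1 3.16-fold (3.09 to 3.22). LDHA, which reduces pyruvate to lactate, was 2.72-fold lower (2.69 to 2.75), ENO1 2.01-fold (2.0 to 2.03) and GAPDH 1.83-fold (1.81 to 1.84). Of 17 gluconeogenesis and insulin signalling genes 14 were lower and 3 higher (median -0.92, below all random lists; adjusted p = 0.209 by camera with an estimated correlation). Besides IGFBP1, PPARGC1A, a coactivator of fasting genes, was 2.30-fold lower (2.1 to 2.53) and pyruvate carboxylase, PC, 1.83-fold lower (1.74 to 1.92). The gluconeogenic enzymes G6PC1, with 143 and 168 reads against 3 and 6, and PCK1, with 38 and 40 against 2 and 2, were chosen after their values were seen and were 39.2-fold (20.4 to 86.5) and 22.1-fold (8.30 to 83.2) lower. The insulin receptor substrate IRS1 was 1.39-fold higher (1.31 to 1.46).

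Other metabolic lists moved less. Fatty acid oxidation and ketogenesis genes were lower in 17 of 21 cases and higher in 3 (median -0.41, percentile 0.01; adjusted p = 0.209 by camera with an estimated correlation). ACAA1 was 1.72-fold lower (1.65 to 1.80) and ACADVL 1.48-fold lower (1.44 to 1.52), but CPT1A, which controls fatty acid entry into mitochondria, was 1.93-fold higher (1.81 to 2.05). Fatty acid synthesis and triglyceride storage genes were split, with 9 higher and 11 lower of 22 (median -0.09, or 0.07 when reads were scaled by plain library size). FASN was 1.43-fold higher (1.41 to 1.45), the acyltransferases GPAM and DGAT2 3.07-fold (2.94 to 3.21) and 2.24-fold (2.13 to 2.35) higher, and the lipid droplet coat PLIN2 2.82-fold lower (2.75 to 2.88). Of 24 cholesterol genes 15 were lower and 5 higher (median -0.18, inside the random range), with MSMO1 1.52-fold lower (1.46 to 1.58) and HMGCS1 1.44-fold higher (1.40 to 1.48). Of 17 cytochrome P450, conjugation and bile acid genes 9 were lower and 5 higher (median -0.23, inside the random range); UGT1A1, which conjugates bilirubin, was 8.40-fold lower (6.18 to 11.6). Of 19 urea cycle and amino acid breakdown genes 11 were lower and 4 higher (median -0.31, percentile 0.74, and -0.20 inside the random range once length, GC and expression trends were removed), and camera did not call them (adjusted p = 0.118, or 0.408 with an estimated correlation). MAT1A was 2.15-fold lower (2.03 to 2.28) and CPS1 1.54-fold higher (1.43 to 1.65).

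Mitochondrially and nuclear encoded transcripts of the respiratory chain moved apart, although camera gave these lists and that of ribosomal proteins an adjusted p = 0.209 with an estimated correlation. Of the 13 mRNAs encoded in mitochondria 12 were higher and 1, MT-ND3, was lower (median 0.61, above all random lists), with MT-ATP6 1.93-fold (1.90 to 1.96) and MT-CO1 1.42-fold (1.41 to 1.44) higher. They took 0.77% and 0.76% of reads in the scramble runs and 1.28% in each shFTO run. Of 38 nuclear encoded oxidative phosphorylation genes 26 were lower and 2 higher, or 3 higher when adjusted over the list alone (median -0.24, percentile 0.2), with UQCRC1 1.51-fold (1.47 to 1.54) and ATP5F1B 1.36-fold (1.33 to 1.38) lower. Cytosolic ribosomal protein transcripts were lower in 47 of 48 cases (median -0.38, below all random lists), none by 2-fold, RPS3 by 1.42-fold (1.41 to 1.44). Across genes with a mean of at least 1 CPM the log2 ratio was related to transcript length (Spearman 0.19, genes not being independent replicates). With length, GC and expression trends removed, the medians moved but stayed outside the random range. They were -0.14 for ribosomal proteins (percentile 0.37), -0.12 for nuclear oxidative phosphorylation (1.63) and 0.91 for mitochondrial mRNAs (100). Mitochondrial mRNAs had a median length of 784 bases against 3571 over all genes, so their corrected value depends on the trend for short transcripts.

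Replication genes were mostly higher, whereas the call of the mitosis list depended on the settings. With an estimated correlation camera gave an adjusted p = 0.209 for the replication and the oxidative stress lists and 0.445 for p53 targets. Of 30 replication and G1/S genes 22 were higher and 1 lower (median 0.25, percentile 99.97), with cyclin D1, CCND1, 2.79-fold higher (2.73 to 2.84) and the replicative helicase subunit MCM5 1.78-fold higher (1.71 to 1.86). Of 30 mitosis and G2/M genes 19 were lower and 6 higher, or 7 higher when adjusted over the list alone (median -0.21, percentile 1.13, and -0.09 at percentile 5.82 after trend removal). The mitosis median was -0.04 with plain library size, and its camera call was lost with plain library size and upper quartile scaling, with the replicate block, without scramble run 1, shFTO run 1 or shFTO run 2, and with an estimated correlation (adjusted p = 0.317 with an estimated correlation). The kinase AURKA was 1.43-fold lower (1.39 to 1.47) and MKI67 1.32-fold higher (1.28 to 1.35). Of 25 p53 targets 19 were higher and 5 lower (median 0.34, above all random lists). The cell cycle inhibitor CDKN1A was 1.96-fold higher (1.88 to 2.04) and MDM2, the ubiquitin ligase of p53, 1.99-fold higher (1.89 to 2.09), whereas GDF15 was 2.15-fold lower (2.07 to 2.24). Of 24 oxidative stress and metal response genes 19 were higher and 4 lower, 6 of them at least 2-fold higher (median 0.32, above all random lists). The aldo-keto reductases AKR1C2, AKR1C1 and AKR1B10 were 4.33-fold (4.22 to 4.44), 2.23-fold (2.19 to 2.27) and 2.31-fold (2.20 to 2.42) higher, the AKR1C values being uncertain because of near-identical copies. The cystine transporter SLC7A11 was 1.75-fold lower (1.56 to 1.97). Of 17 Wnt targets 11 were higher and 5 lower (median 0.49, above all random lists), but camera did not call the list (adjusted p = 0.106, or 0.408 with an estimated correlation). Among them were AXIN2, 1.95-fold higher (1.88 to 2.04), NKD1, 1.72-fold higher (1.68 to 1.75), and the Wnt inhibitor DKK1, 2.71-fold lower (2.66 to 2.76).

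The rest of the m6A machinery differed little. Of 22 genes 12 were higher and 4 lower, none by 2-fold (median 0.10, percentile 90.57). METTL16 was 1.6-fold higher (1.49 to 1.71) and YTHDF1 1.34-fold higher (1.29 to 1.40), while the catalytic subunit METTL3 was 1.38-fold lower (1.31 to 1.46). The other demethylase, ALKBH5, was 1.13-fold lower (1.08 to 1.18), a log2 ratio of -0.18 that became -0.01 and did not pass when reads were scaled by plain library size. Among 5 tested genes near FTO none was higher and 3 were lower, or 4 when adjusted over the list alone (median -0.23, inside the random range). IRX3, a homeobox gene known for its link to obesity variants within FTO, was 2.1-fold lower (1.99 to 2.21).

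Most markers of other cell types were too low to test. Of 12 fibroblast and stellate cell markers 3 were tested, with COL1A1 23.8-fold higher (9.95 to 74.5) at 3.12 CPM and PDGFRB 6.42-fold lower (5.42 to 7.66). Of 12 endothelial markers 2 were tested, TIE1 2.41-fold higher (1.57 to 3.79) and ENG 3.59-fold lower (2.24 to 5.95), and of 12 neural and kidney line markers 3 were tested, 2 lower and none higher. The lower pair, TUBB3 and PAX8, did not pass with DESeq2. Of 12 leukocyte markers 7 were tested, 2 higher and 4 lower (median -0.73, inside the random range). LYZ, the lysozyme gene, went from 3005 to 232 CPM and was 12.9-fold lower (12.7 to 13.2), and ITGAM had 0.0262 CPM in scramble and 0.692 CPM in shFTO.

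**Figure D3:**
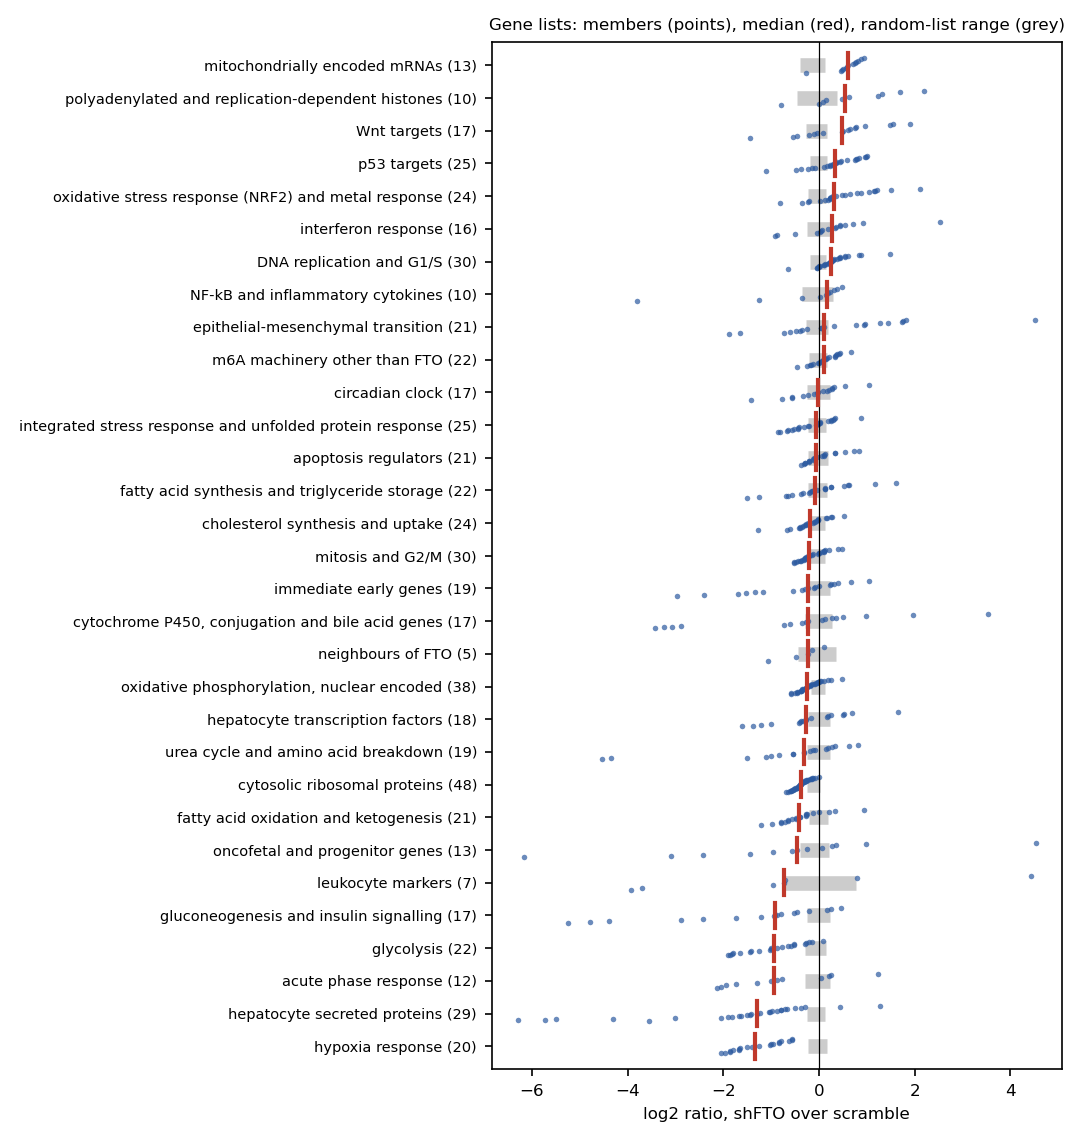
Log2 ratio of shFTO over scramble (horizontal axis) for the tested members of the 31 lists with at least 5 of them (blue points, genes without reads in 1 group drawn at their bound), with each list's median in red and the central 95% of medians of 10000 random lists in grey. Numbers in brackets are tested members, and the hypoxia median of -1.33 and the secreted protein median of -1.29 lie furthest to the left.

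With camera at a preset correlation of 0.01, 4 of the 31 lists were called higher (mitochondrial mRNAs, DNA replication, p53 targets and oxidative stress) and 8 lower (secreted proteins, hypoxia, glycolysis, gluconeogenesis, fatty acid oxidation, nuclear oxidative phosphorylation, ribosomal proteins and mitosis). No call held with an estimated correlation: camera gave an adjusted p = 0.209 with an estimated correlation for each of them except mitosis (0.317) and p53 targets (0.445). That setting had 2 residual degrees of freedom and an estimate taken from runs that differ by sampling noise. Even the ribosomal list, with 47 of 48 members lower, had an unadjusted p = 0.0128 by camera there. Losing every call therefore does not tell whether correlation between genes accounts for the calls. These tests too compare 1 library pool with another. Scaling by plain library size raised the median log2 ratio of all genes from 0.009 to 0.177 and the share of calls that were higher from 49.9% to 68.8%, so directions are relative to the bulk of genes.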

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

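Scaling by plain library size, summed runs with an assumed coefficient of variation, the random-list criterion and trend removal were chosen after the data were seen. The FTO log2 ratio and the 4 counts of changed genes kept their direction and stayed within 1.5 times under RLE and upper quartile scaling, both filters, DESeq2 and limma-voom. Without 1 run, the FTO level ran from -2.48 to -2.34, and genes at least 2-fold changed numbered 1579 to 1650 (1551 with all runs, 1385 to 1420 shared). Plain library size gave 3041 as the number of genes lower and turned IGF2BP2 to 0.04 and SCD to 0.02, because it shifts all genes. Summed runs with an assumed coefficient of variation of 0.2 gave 391 higher and 500 lower genes, all at least 2-fold. An assumed 0.4 gave 55 and 61 and left the FTO ratio of -2.41 short of the threshold. At 0.2, 15 secreted protein, 10 hypoxia and 8 glycolysis genes still passed as lower, and no ribosomal, mitochondrial or p53 gene did. At 0.4 the numbers were 5, 0 and 0. Estimated correlation, with 2 residual degrees of freedom, left 0 lists higher and 0 lower. Fry, which does not compare a list with other genes, called 8 higher and 20 lower, and turned the NF-kB list to lower (adjusted p 0.0015), whose median is above 0 and whose mean is below. Trend removal put the medians of oncofetal genes (-0.25), urea cycle (-0.20) and mitosis (-0.09) inside the random range and that of epithelial-mesenchymal transition (0.26) outside it. The mitosis call of camera was also lost with upper quartile and plain library size scaling, with the replicate block and without scramble run 1, shFTO run 1 or shFTO run 2, and an acute phase call was gained with those scalings, without the filter and without either shFTO run. Calls were also gained for the oncofetal, cholesterol and urea cycle lists without the filter, and for the m6A machinery with plain library size. The cause was not tested. A lone run was assumed to vary like the other group.

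Whether the replicate numbers pair the samples could not be told. The run differences of the groups correlated at -0.001 over 5737 genes. As runs of a group did not differ detectably beyond sampling noise, that value would lie near 0 with or without pairing. With the replicate block 1551 genes were at least 2-fold changed, 1550 of them shared with the fit without it, and 7 lists in place of 8 were lower. Depth limits low genes most: folds of genes with a handful of reads have intervals spanning several-fold.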

Other observations

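Growth factor response, matrix and inflammatory genes, lists not described so far, were split between higher and lower members. Of 19 immediate early genes 12 were lower and 5 higher, or 6 higher when adjusted over the list alone (median -0.23, percentile 3.37 of random lists). DUSP6, a phosphatase induced by ERK signalling, was 7.84-fold lower (7.28 to 8.44), IER3 2.89-fold lower (2.80 to 2.97) and EGR1 2.24-fold lower (1.87 to 2.69), whereas JUN was 1.59-fold higher (1.52 to 1.65). Of 21 epithelial-mesenchymal transition genes 10 were higher and 8 lower, or 11 higher when adjusted over the list alone (median 0.10, inside the random range). The matrix protein THBS1 was 3.34-fold higher (3.22 to 3.46) and N-cadherin, CDH2, 2.44-fold higher (2.30 to 2.58), while CCN2 was 3.66-fold lower (3.54 to 3.78) and fibronectin, FN1, 1.66-fold lower (1.66 to 1.67). Of 10 NF-kB and cytokine genes 4 were higher and 3 lower. Their median was 0.16 and their mean -0.37, as the chemokine CCL20 was 14-fold lower (13.2 to 14.9) and ICAM1 2.38-fold lower (2.28 to 2.5).

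Of 16 interferon response genes 8 were higher and 3 lower (median 0.27, inside the random range), with MX1 1.88-fold higher (1.58 to 2.26). Of 10 histone genes 7 were higher and 1 lower (median 0.55, percentile 99.74, with a camera adjusted p = 0.116, or 0.49 with an estimated correlation), with H2AC6 2.34-fold higher (1.92 to 2.87). Histone values are uncertain, since copies share sequence and many lack a poly(A) tail. Of 25 integrated stress and unfolded protein response genes 6 were higher and 12 lower, of 17 circadian clock genes 6 were higher and 5 lower, and of 21 apoptosis regulators 6 were higher and 10 lower. Their medians were -0.06, -0.02 and -0.07, inside the random ranges, and 0.11, 0.15 and 0.09 with plain library size, and the mean of the apoptosis list was 0.04. The chaperone HSP90B1 was 1.57-fold lower (1.56 to 1.58), the clock repressor BHLHE40 2.66-fold lower (2.58 to 2.75) and the cell death gene BCL2L11 1.67-fold higher (1.56 to 1.79).

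In the tests that follow, those on the share of hepatocyte-like cells, on the knockdown itself, on oxygen or density and on the chance order of genes were chosen after the results they bear on were seen. The lower level of secreted protein transcripts (median log2 ratio -1.29 over 29 genes) stayed at -1.17 after transcript length, GC and expression trends were removed, which argues against those trends as the whole cause. A lower share of hepatocyte-like cells would lower all members by about 1 common factor only if the other cells lacked each of them, which was not measured. The members did not change by 1 factor. Of the 29, 8 lay more than 2-fold from the list's median change, among them FGA at 78.9-fold lower and KNG1 at 2.42-fold higher. The lowest fitted log2 ratio was that of PLG (-7.06), a gene with 31 scramble reads and none in shFTO. Random lists matched on expression had a median of 2, and 27 of 10000 reached 8. Those lists were drawn from all other tested genes, most of which moved little, and they treat genes as independent. The test therefore cannot decide, and a changed share stays open. The measure replaced an earlier comparison with counting intervals whose outcome the depth alone had set. Whether the FTO knockdown itself gave the change stays open, because each group was counted as 1 independent sample, with 1 shRNA.

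The 39 genes of the hypoxia and glycolysis lists had a median of -1.01, and -0.85 after trend removal, which argues against length, GC and expression trends as the whole cause. Of these 39, 38 were not among the genes of the chromosome segments described next, so copy number differences there cannot account for the lower median. The median of those 38 was -1.01, but leaving out so few genes could hardly have moved it. Oxygen or cell density in culture could lower the same genes and cannot be told apart from the knockdown, since each group was counted as 1 independent sample.

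Runs of neighbouring genes were lower on 3 chromosomes: from LSM6 to CDKN2AIP on chromosome 4 (42 genes, median -0.42), from CILK1 to ASCC3 on chromosome 6 (58 genes, -0.39) and from CCNB1IP1 to RPS29 on chromosome 14 (92 genes, -0.43). Of these 192 genes 84.9% were below 0, which follows from picking them by low window medians and is no separate support. The windows were picked as lying below -0.43, the lowest window median in 1000 shuffles of the gene order. That 0 shuffles reached the lowest observed window median of -0.48 is therefore the same comparison and not a second one. It argues against chance order for the lowest window. The same picked genes had a median of -0.33 after trend removal, which argues against length, GC and expression trends as the whole cause. A copy number difference between the lines is a candidate explanation, checked on 44 genes of the segments at 1 to 8 CPM, not used to find them. Among these 44, 61.4% lay below 0 against 45.3% of 2139 such genes elsewhere, with medians of -0.33 and 0.07. The share was short of the 65% set in advance and above the 55% that would have argued against a copy number difference, so that explanation stays open. The segments hold 16 of the 354 scanned genes that were at least 2-fold lower, or 4.5%, with 2.1% of all scanned genes.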
